A study of Mus musculus with 6 samples.

How the data were processed

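RNA was measured in 6 libraries of sorted hair follicle cells from the back skin of newborn mice (postnatal day 0), 3 from control animals and 3 from Ring1a-/- Ring1b-/I53A mutants. Per the labels' protocols, the skin was digested with collagenase and trypsin, cells were stained for Sca1, α6-integrin and EpCAM and sorted. Per the same protocols, 10 ng of total RNA per library was reverse transcribed and amplified with a low-input kit before 100 ng of sheared cDNA entered library construction. Sequencing on an Illumina HiSeq instrument gave single reads of 100 nucleotides. The protocol text describes a Sca1-positive gate for interfollicular epidermis, while the title, source and cell type labels of every sample say hair follicle. The gate used for these samples is not given in the sources used here. The labels do not say whether the 3 samples of a group came from separate animals. Xist and Ddx3y put both sexes in each group, so that not all libraries of a group came from 1 animal, while libraries of the same sex may share one and part of the spread behind the p-values may be technical.

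The deposited files hold whole-number read counts per gene symbol, 1 file per library, with no normalization, as the values show. Per the submitters' processing notes, the reads were handled with TopHat2 2.0.13, Cufflinks 2.2.1, HTSeq 0.6.1 and DESeq2 1.6.3 on mm10. The notes as used here give no role or order of these tools, and the strand setting and annotation release are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart, and a count for a gene with near-identical copies may hold reads of its relatives. Each file lists 24453 symbols, and none of the symbols is a summary line such as unassigned reads.

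Library totals ran from 14335156 to 18811587 counts, so that a counts-per-million (CPM) value of 1 was 14.7 to 18.3 reads. A count of 0 allows a level of up to 3 counts, which is 0.164 to 0.204 CPM in these libraries. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The 15 pairs of libraries differed by a chi-square per degree of freedom of at least 26.1, so no pair agreed within sampling noise.

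Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter, group as the only term and Benjamini-Hochberg adjustment over the 14345 genes tested. A gene was called at an adjusted p under 0.05, two-sided. The filter removed 0.0971% of all counts. CPM values use TMM effective library sizes, the standard error (SE) of a log2 fold change was taken from the F statistic, and levels are given as mean ± SD with n = 3 libraries per group. Where a group held 1 to 3 reads of a gene in all, the ratio of CPM is given with an exact 95% interval from the counts, because the fitted fold change then depends on the prior count. Sets of genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the 32 lists with at least 3 tested members. The same test with an estimated correlation and the rotation test fry were run beside it. The 33 lists, the design and the alternatives were fixed before the data were examined, except for the additions named with the closing results. The genes named are Ring1 and Rnf2, the 3 genes of the sort (Epcam, Itga6 and Ly6a), and the 8 genes with the largest rise and the 8 with the largest fall in log2 fold change among called genes. The last 2 sets were limited to genes without overlap between groups and with at least 5 CPM in the higher group, passing over unnamed models and sex genes. Of the 8 largest rises, 1 gene is not reported here. From each list up to 4 members are named, called ones first and then by the smallest p, with further uncalled members given where useful. Dlx5, Onecut2 and Lmx1a, the remaining risen members of their list, were outside this rule and were added after their values were seen, as was Lrp3.

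The labels give both groups the replicate numbers 1 to 3 without saying what a number marks. The deviations of same-numbered libraries from their group means correlated at 0.168 to 0.363, against at most 0.0891 for other pairs of a control and a mutant library, with the sex genes left out. All 6 libraries correlated best with the library of their own number. The pairing therefore comes from the data, by a minimum correlation of 0.1 set in advance. The deviations within a group cancel out for each gene, so the matches of the 6 libraries are not independent of each other. Few matchings of 3 with 3 libraries exist, so chance alone could give this one, and the pairing stays uncertain. A fit with the replicate number as a block is given beside a result where it changed the call or moved a count by over 1.5 times.

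The same steps were tested on simulated data before use. For the comparison of mutant with control, on 14025 simulated genes, 21 of 100 genes with a 2-fold change and 75 of 100 with a 4-fold change were recovered, with 6 false calls. A simulated list with a shift of 0.5 on the log2 scale was called, and 0 of 32 other lists were. The simulated genes varied independently and the lists held random genes. The simulation therefore does not show how the list test behaves where members vary together. The alternatives were other scalings (size factors of the DESeq2 type, upper-quartile factors, totals alone), no filter and a stricter filter. Further ones were DESeq2 1.42.0, limma-voom, the replicate block, leaving out each library, an adjusted p under 0.01 and a test against a fold of 1.5. Corrections for GC content and transcript length were added after the data were seen, as were a term for Y-linked expression and fits without the sex genes and the ribosomal RNA precursor Rn45s or without both libraries numbered 3. GC content and length came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, and covered 98.0% of the tested genes. Gene coordinates are 1-based on the same assembly. Figures were drawn with matplotlib 3.10.9.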

Results

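Gene expression was measured by RNA sequencing in hair follicle cells sorted from the back skin of newborn mice, 3 control libraries and 3 libraries of the genotype Ring1a-/- Ring1b-/I53A. Ring1a is encoded by Ring1 and Ring1b by Rnf2, the E3 ubiquitin ligases of Polycomb repressive complex 1 (PRC1). The I53A allele is known to impair the ligase activity of Ring1b towards histones while leaving the protein in place. The comparison asks how follicle cells of this genotype differ from controls. It joins loss of Ring1a and a null allele of Ring1b with the I53A allele, no group separates these, and the labels name the other genotype only as control. Library totals were 14335156, 16090974 and 18811587 counts in the controls and 17278824, 16152813 and 15661124 in the mutants. They did not separate the groups (exact permutation test, two-sided, p = 1, where 3 against 3 allows no p under 0.1). The first principal component of log2 CPM held 45.3% of the variance and the second 22.1%.

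Transcript of Ring1 (chromosome 17, 34020792 to 34024680, minus strand, GRCm38) was lower in every mutant library. Counts were 247, 352 and 372 reads in the controls and 59, 119 and 73 reads in the mutants, or 16.8, 22.1 and 21.1 CPM against 3.23, 7.09 and 4.88 CPM. The mean fell from 20.01 ± 2.80 to 5.07 ± 1.94 CPM (SD, n = 3 each), a log2 fold change of -1.98 (SE 0.33, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0113). Rnf2 (chromosome 1, 151458004 to 151500955, minus strand), the gene of the I53A allele, was at 59.8 ± 6.93 CPM in controls and 67.1 ± 3.68 CPM in mutants. It did not pass the test (log2 fold change 0.17, SE 0.17, adjusted p = 0.736). The parts of Ring1 and Rnf2 missing from their null alleles are not given in the sources used here. A null allele may keep reads outside its missing part, so the unlowered level of Rnf2 neither bears out nor rules out its null allele. Gene counts do not show the substituted codon of Rnf2, and Rnf2 overlaps Trmt1l on the other strand.

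**Figure D1:**
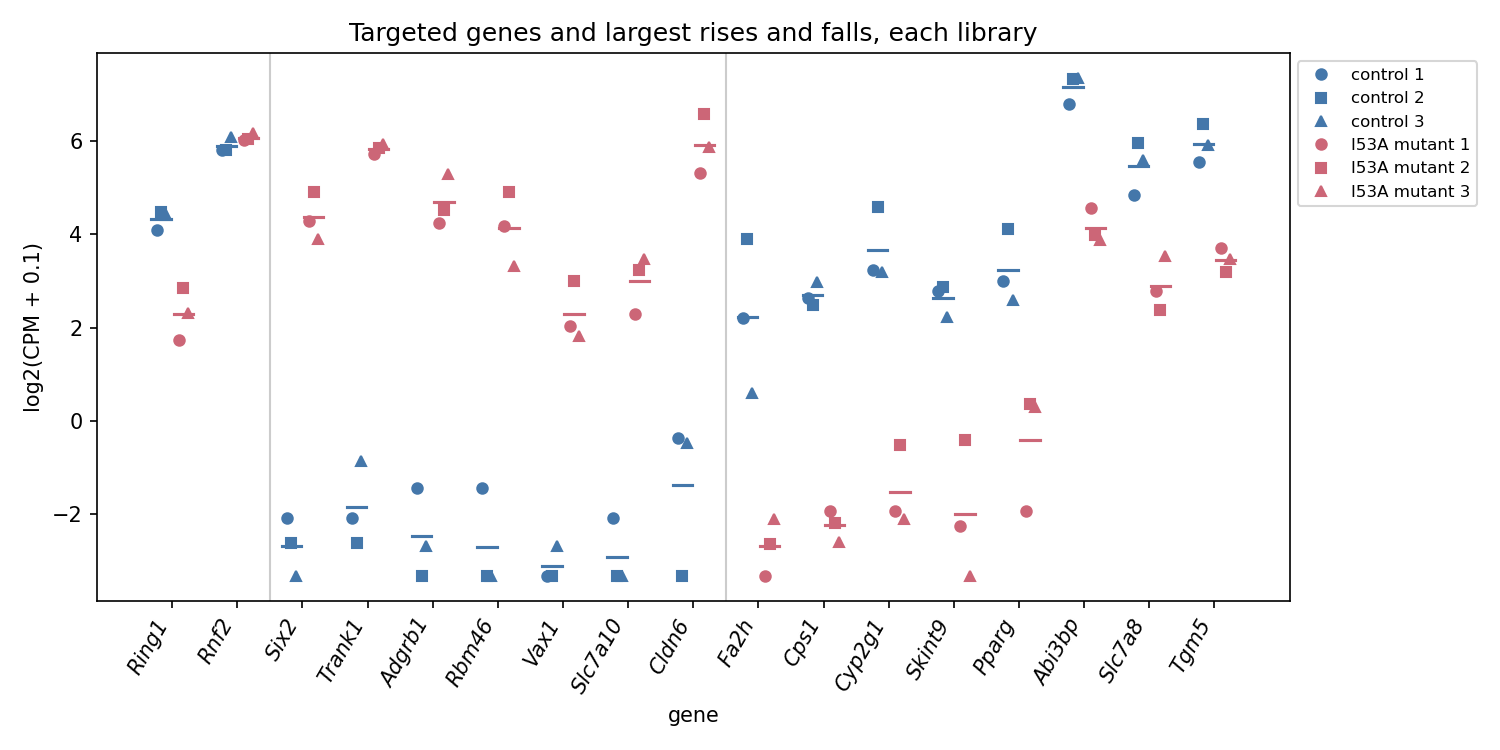
Levels of Ring1, Rnf2, 7 of the 8 genes with the largest rise and the 8 with the largest fall in each library, as log2(CPM + 0.1); colours mark the groups, symbols the replicate numbers and short bars the mean of the 3 values. The groups are apart for every gene shown except Rnf2, which was a condition for choosing the largest rises and falls.

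Several developmental regulators that were almost silent in control follicle cells were transcribed in the mutants. Six2, a homeobox factor of nephron progenitors (chromosome 17, 85684277 to 85688274), had 3 reads over the control libraries and 1081 over the mutant ones. The ratio of CPM was 348 (95% interval 119 to 1.69e+03), with levels of 0.0663 ± 0.0682 and 21.5 ± 7.80 CPM (log2 fold change 8.26, SE 0.62, adjusted p = 0.000352). Vax1, a homeobox gene of the forebrain and optic nerve (chromosome 19, 59166187 to 59170056), reached 5.11 ± 2.46 CPM, a ratio of 248 (44.1 to 9.83e+03). Its adjusted p was 0.00297. Rbm46, an RNA-binding protein of germ cells needed for meiosis (chromosome 3, 82837228 to 82876483), rose from 0.0908 to 19.3 ± 10.2 CPM (log2 fold change 7.72, SE 0.84, adjusted p = 0.00127). Its 4 control reads were all in control 1, and without 1 library its log2 fold change ran from 7.12 to 11.3.

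Genes of other kinds rose as strongly. Trank1 (chromosome 9, 111311739 to 111395775) went from 0.218 ± 0.208 to 56.7 ± 4.21 CPM (log2 fold change 7.92, SE 0.43, adjusted p = 3.19e-05). The adhesion receptor gene Adgrb1 (chromosome 15, 74516195 to 74589465) went from 0.110 ± 0.144 to 26.9 ± 10.8 CPM (7.91, SE 0.65, adjusted p = 0.000411). Cldn6, a tight junction claudin of embryonic epithelia (chromosome 17, 23679249 to 23682446), rose from 0.435 ± 0.378 to 64.4 ± 28.6 CPM (7.18, SE 0.65, adjusted p = 0.000526). Slc7a10, an amino acid transporter (chromosome 7, 35186385 to 35201114), rose to 8.30 ± 3.17 CPM, a ratio of 195 (53.8 to 1.62e+03), with an adjusted p of 0.00218. It overlaps Lrp3 on the opposite strand, which itself rose from 3.41 ± 0.216 to 30.5 ± 3.87 CPM (3.16, SE 0.24, adjusted p = 0.000352), so reads of this pair may be shared.

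Of the 14345 genes tested, 430 changed, 372 of them upward and 58 downward, and 389 changed at least 2-fold (353 up and 36 down). The risen genes were mostly low in controls, with a median of 4.43 CPM against 21.3 CPM in mutants, and 90 of them were under 1 CPM in controls. The fallen genes had medians of 103 and 41.6 CPM. All tested genes had a control median of 17.4 CPM, and 1029 of them were under 1 CPM in controls. A gene near the floor in controls can hardly be called as fallen, so part of the contrast between risen and fallen genes follows from detection. Upward calls were 86.5% of the total, and 2143 genes had an unadjusted p under 0.05. The groups did not overlap for any of the 430, or for 3044 genes (21.2%) in all, where chance gives 10%. With the replicate number as a block 1345 genes were called, 873 up and 472 down (64.9% up), among them all 430, and DESeq2 called 959 (728 up and 231 down). Without control 1, 2 or 3 the count was 193, 277 and 664, and without mutant 1, 2 or 3 it was 218, 163 and 331, with more genes up than down each time.

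**Figure D2:**
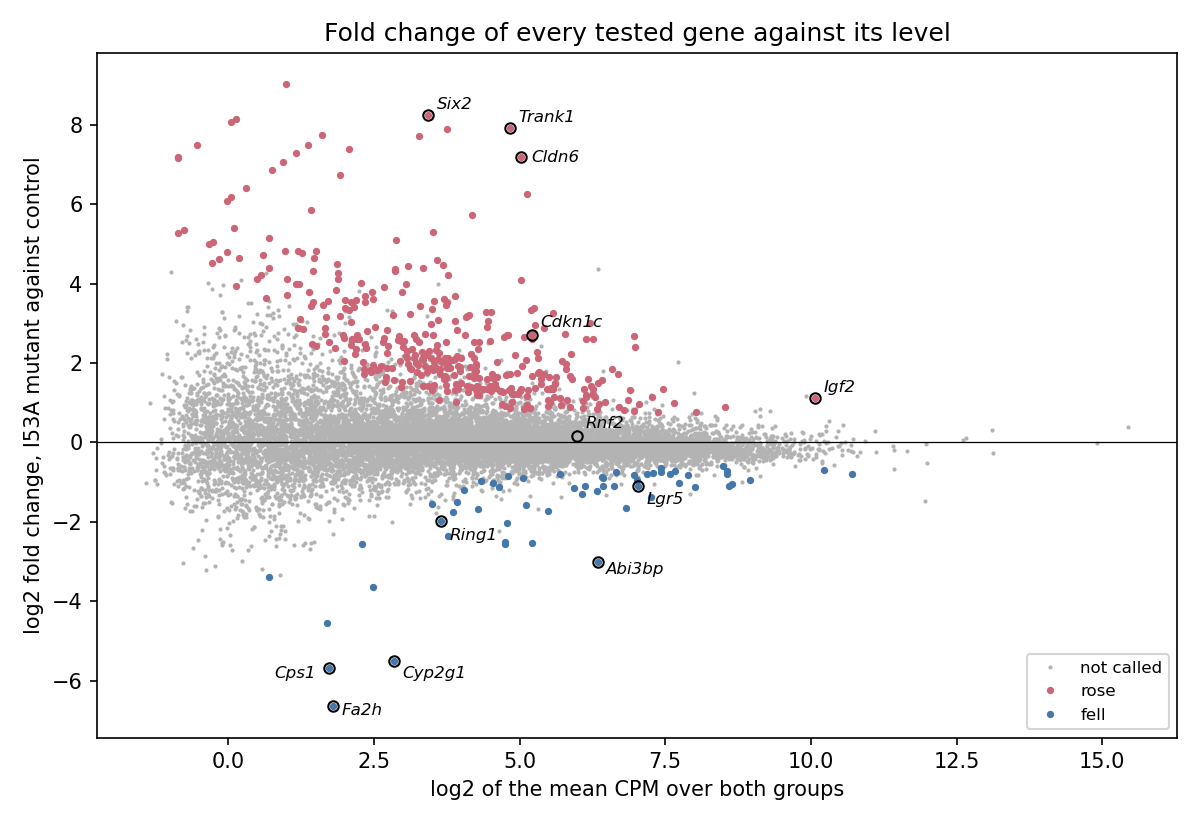
Log2 fold change (mutant against control) of each of the 14345 tested genes against the log2 of its mean CPM over both groups; red points rose, blue points fell and grey points were not called. Calls above 0 (372) outnumber those below (58) and lie mainly at low to middle levels; Igf2 was labelled after its value was seen.

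The 8 largest falls lay between -6.65 and -2.52 on the log2 scale. Fa2h, which 2-hydroxylates fatty acids (chromosome 8, 111345135 to 111393824), went from 6.89 ± 6.98 to 0.0644 ± 0.0670 CPM, a ratio of 0.00888 (0.00182 to 0.0262, adjusted p = 0.0136). Pparg, the nuclear receptor of sebocytes and adipocytes (chromosome 6, 115360951 to 115490399), fell from 10.3 ± 5.95 to 0.831 ± 0.578 CPM (log2 fold change -3.63, SE 0.69, adjusted p = 0.0215). Cps1, an enzyme of the urea cycle (chromosome 1, 67123026 to 67231259), fell from 6.48 ± 1.17 to 0.117 ± 0.0488 CPM (-5.68, SE 0.59, adjusted p = 0.00103). Cyp2g1 (chromosome 7, 26808892 to 26821205) fell from 14.1 ± 8.52 to 0.298 ± 0.259 CPM (-5.52, SE 0.67, adjusted p = 0.00247). Abi3bp, an extracellular matrix protein (chromosome 16, 56477878 to 56690135), fell from 144 ± 29.4 to 17.9 ± 4.84 CPM (-3.01, SE 0.25, adjusted p = 0.000415). Tgm5, a transglutaminase of the cornified envelope (chromosome 2, 121046111 to 121085841), fell from 63.0 ± 17.6 to 10.97 ± 1.94 CPM (-2.52, SE 0.26, adjusted p = 0.000994). The amino acid transporter Slc7a8 (chromosome 14, 54722209 to 54781946) fell from 46.1 ± 16.8 to 7.81 ± 3.36 CPM (-2.57, SE 0.37, adjusted p = 0.0063). Skint9 (chromosome 4, 112385969 to 112433985) dropped from 6.19 ± 1.39 to 0.255 ± 0.351 CPM (-4.54, SE 0.89, adjusted p = 0.0245). It belongs to a multigene family whose reads may be split between members. Of these 8, Fa2h, Skint9 and Pparg were not called in 2, 3 and 3 of the 6 fits without 1 library. Their highest adjusted p were 0.0731 (without mutant 2), 0.101 (without mutant 1) and 0.0803 (without control 2). Fa2h and Pparg also lost their calls with limma-voom (0.128 and 0.0588).

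Transcription factors of other lineages were among the risen genes. Of 18 tested neural and sensory lineage factors (69 listed), 7 rose and none fell: Vax1, Sim2, Lmx1b, Irx6, Dlx5, Onecut2 and Lmx1a. Sim2 had 1 read in controls and 165 in mutants (ratio 159, 28.2 to 6.33e+03, adjusted p = 0.00761) and Irx6 a ratio of 94.6 (16.6 to 3.77e+03, adjusted p = 0.0179). Lmx1b, a LIM homeobox factor of limb and midbrain, rose from 6.26 to 19.98 CPM (1.67, SE 0.27, adjusted p = 0.0110). Irx3 was at 4.87 and 19.5 CPM and passed with the replicate block alone (adjusted p = 0.0553, and 0.00397 with the block). Adjusted over the list alone, 10 rose and 3 fell, and with the block 11 rose and 1 fell. The median log2 fold change was 1.78 (camera, adjusted p = 2.59e-06; adjusted p = 0.491 with an estimated correlation). Of 20 tested factors of mesoderm, muscle, limb and endoderm (68 listed), 4 rose, among them Six2, Osr1 and Tbx3. Osr1, a factor of kidney and limb mesoderm, rose from 0.675 to 7.91 ± 5.03 CPM (3.54, SE 0.58, adjusted p = 0.0115). Tbx3, a T-box factor of limb and mammary development, rose from 1.93 ± 2.18 to 23.9 ± 3.47 CPM (3.61, SE 0.72, adjusted p = 0.0267). Without 1 library the log2 fold change of Tbx3 ran from 3.07 to 5.10. Adjusted over this list alone, 6 rose and 1 fell, and with the block 5 rose and 1 fell. The median was 0.83 (adjusted p = 0.00138; adjusted p = 0.447 with an estimated correlation). In fits without 1 library, Lmx1b was not called in 2 of 6, and Irx6 and Tbx3 in 4 of 6 each. The highest adjusted p were 0.0593 and 0.106 without mutant 2 and 0.119 without control 1. Osr1 lost its call with limma-voom (0.0656).

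Among 29 tested Hox genes (39 listed), which set position along the body axis, 2 rose and none fell, also when adjusted over the list alone. Hoxc10 went from 0.404 to 14.3 ± 2.44 CPM (5.10, SE 0.44, adjusted p = 0.000488) and Hoxd9 from 0.0833 to 5.25 ± 1.90 CPM (5.86, SE 0.81, adjusted p = 0.00508). The list had a median of 0.21 and passed weakly (adjusted p = 0.0406; adjusted p = 0.879 with an estimated correlation), and it did not pass with the replicate block (adjusted p = 0.0960). It also did not pass without control 3 (0.0999), mutant 1 (0.0605) or mutant 2 (0.209). Over all alternatives the median of the Hox list ran from 0.07 to 0.57. Of 11 tested dermal papilla genes (18 listed), 1 rose, against 3 adjusted over the list alone and 3 with the block. The median was 0.93 (adjusted p = 0.0027; adjusted p = 0.491 with an estimated correlation). The list did not pass without control 1 (0.0820) or mutant 3 (0.0642). Such list tests also passed in other groupings of the libraries, up to 17 lists in one of them against 5 of 32 here. No list passed with an estimated correlation.

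**Figure D3:**
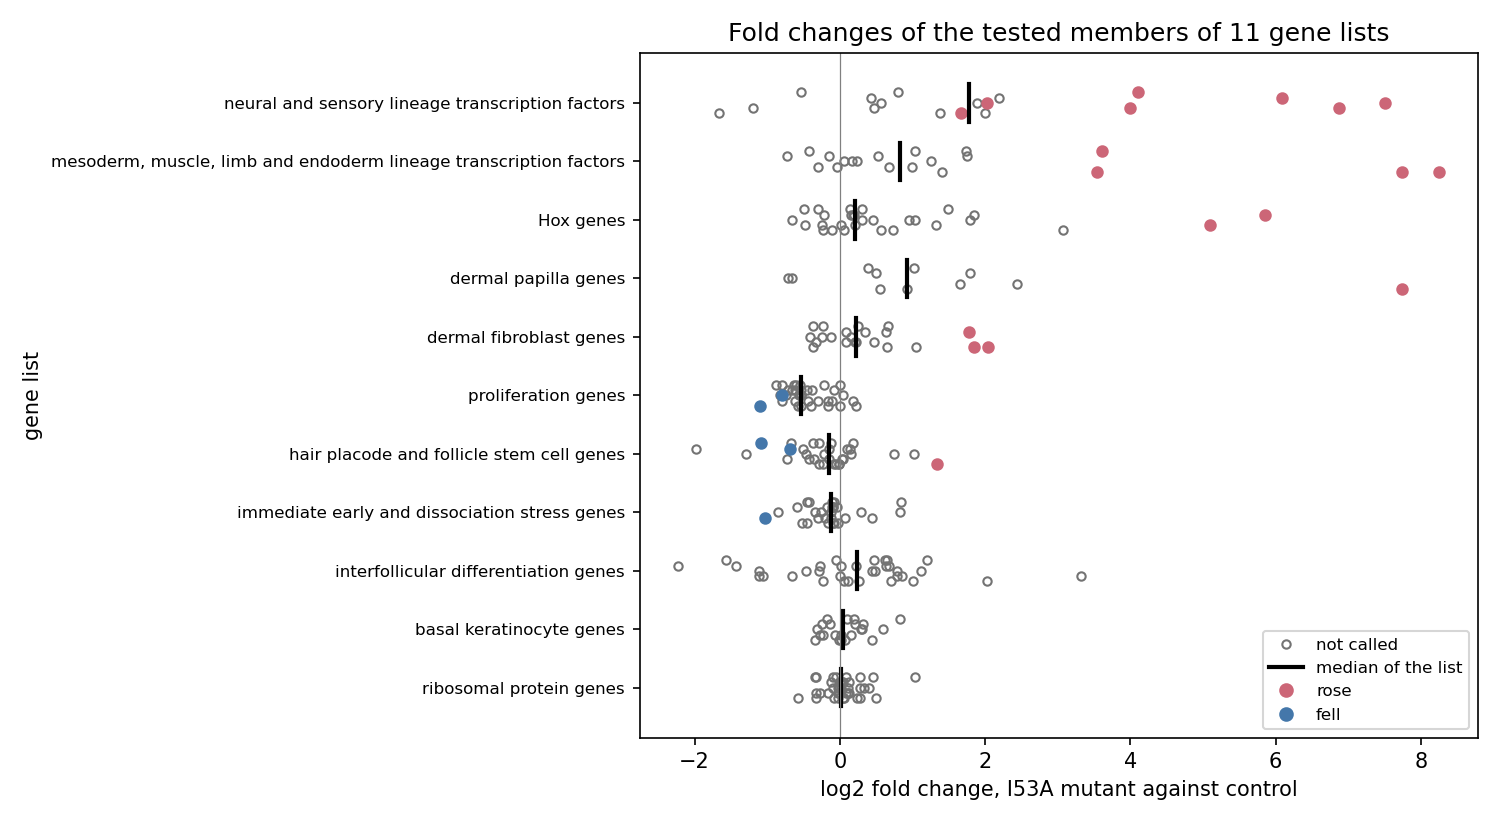
Log2 fold change of the tested members of 11 gene lists; open circles were not called, red points rose, blue points fell and black bars mark the list medians. The medians of the neural and sensory factors (1.78) and the proliferation genes (-0.54) lie farthest above and below 0 in this plot.

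Proliferation genes were lower in the mutant follicle cells, 30 of 35 with a negative log2 fold change and a median of -0.54 (camera, adjusted p = 3.4e-07; adjusted p = 0.491 with an estimated correlation and 0.0954 with fry). Mcm6, a subunit of the replicative helicase, fell from 118 ± 25.7 to 54.8 ± 9.75 CPM (-1.11, SE 0.21, adjusted p = 0.0239). The proliferation marker Mki67 fell from 2120 ± 375 to 1219 ± 130 CPM (-0.80, SE 0.17, adjusted p = 0.0408). Those 2 were the only members called over all genes, 9 fell when adjusted over the list alone and 13 with the replicate block. Mki67 was called in none of the 6 fits without 1 library and Mcm6 in 1, with adjusted p up to 0.164 without mutant 2 and 0.111 without control 1. Mki67 also lost its call with the stricter filter (0.0503).

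Of 31 tested hair placode and follicle stem cell genes (33 listed), 1 rose and 2 fell, against 3 and 3 adjusted over the list alone and 3 and 8 with the replicate block. Lgr5, a Wnt pathway receptor of follicle stem cells, fell from 178 ± 37.7 to 83.7 ± 1.98 CPM (-1.09, SE 0.18, adjusted p = 0.0125). The transcription factor gene Nfib fell from 1478 ± 104 to 916 ± 99.0 CPM (-0.69, SE 0.15, adjusted p = 0.0396). The chemokine gene Cxcl14 rose from 100 ± 36.4 to 254 ± 72.4 CPM (1.34, SE 0.30, adjusted p = 0.0457). Sox9 (536 and 575 CPM), Krt15 (1068 and 1101 CPM) and Lhx2 (334 and 248 CPM) were not called. The list median was -0.15 (adjusted p = 0.0827, 0.879 with an estimated correlation and 0.0321 with the block), and the list passed without control 1 (0.0121) or mutant 3 (0.0404). Without 1 library Lgr5, Nfib and Cxcl14 were called in 3, 1 and 1 of 6 fits. Their highest adjusted p were 0.0684 and 0.127 without mutant 2 and 0.159 without mutant 1. Nfib also lost its call with library totals only (0.0631) and Cxcl14 with DESeq2-type size factors (0.0539), and both with the GC and length correction (0.0653 and 0.0640). Of 23 tested inner root sheath, companion layer and hair shaft genes (38 listed), 1 rose over all genes. Adjusted over the list alone 4 rose and 1 fell, and with the block 5 rose and 1 fell (median 0.16, adjusted p = 0.760). That gene, the hair keratin Krt85, had 2 reads in controls and 80 in mutants (ratio 38.6, 10.3 to 324, adjusted p = 0.0309). It lost its call without any 1 library (up to 0.159 without mutant 1), and reads of related keratins may be shared with it. Krt6a, a companion layer keratin, was at 7.40 ± 8.26 and 154 ± 213 CPM, the mutant mean resting on mutant 3 (399.8 CPM). Its adjusted p was 0.0822, or 0.000178 with the block.

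Layers of the epidermis showed few calls. None of 34 tested interfollicular differentiation genes (39 listed) was called, nor when adjusted over the list alone (median 0.24, adjusted p = 0.825), against 7 up and 3 down with the replicate block. Krt1, of the suprabasal layers, was at 3358 and 2126 CPM (-0.66, adjusted p = 0.195, and 0.00154 with the block). None of 22 basal keratinocyte genes was called, nor when adjusted over the list alone (4 up with the block). The median was 0.04 with a camera direction below 0 (adjusted p = 0.980). Krt5, the main basal keratin, was at 7911 ± 804 and 9845 ± 1706 CPM (adjusted p = 0.477, and 0.0476 with the block). Of 27 hemidesmosome and basement membrane genes, 1 rose, also adjusted over the list alone, and the median was 0.04 (adjusted p = 0.825; 1 up and 1 down with the block). Nid1, a basement membrane linker, rose from 40.6 ± 14.6 to 109 ± 16.6 CPM (1.42, SE 0.26, adjusted p = 0.0187). It was called in 2 of 6 fits without 1 library (up to 0.0825 without control 2). Of 19 tested desmosome and adherens junction genes none was called, nor when adjusted over the list alone (median 0.17, adjusted p = 0.17). With the block 5 rose, among them Pkp2 (3.68 and 15.4 CPM, adjusted p = 0.0875, and 0.00201 with the block). The list passed without control 3 (0.0293) or mutant 1 (0.0433). None of 17 tested Merkel cell genes (30 listed) was called, nor when adjusted over the list alone (median -0.19, adjusted p = 0.825). Atoh1, which specifies these cells, was at 2.64 and 1.86 CPM, and Sostdc1 at 345 and 141 CPM (adjusted p = 0.0805, and 0.000252 with the block, the 1 member then called).

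In the signalling lists, 1 of 18 tested Wnt target genes rose, also adjusted over the list alone. Nkd2, an antagonist of the pathway, went from 4.25 to 11.3 CPM (1.41, SE 0.32, adjusted p = 0.0476). It was called in 1 of 6 fits without 1 library (up to 0.175 without mutant 2) and lost its call with upper-quartile factors (0.0528), the sex term (0.0603) and the GC and length correction (0.0549). The list median was 0.02 (adjusted p = 0.721), with 2 up under the block, and Axin2 and Lef1 were not called. None of 16 tested Hedgehog genes was called, nor when adjusted over the list alone (median -0.15, adjusted p = 0.400). Shh, the ligand and the 1 member called with the block, was at 101 ± 51.4 and 60.6 ± 31.4 CPM (adjusted p = 0.521, and 0.0056 with the block). Of 24 tested TGF-beta and BMP genes 2 rose, against 3 up and 2 down adjusted over the list alone and 3 up and 5 down with the block. Those were the ligand genes Bmp4 (36.2 to 76.3 ± 11.2 CPM, 1.07, SE 0.18, adjusted p = 0.0115) and Tgfb2 (134 to 269 ± 61.4 CPM, 1.00, SE 0.22, adjusted p = 0.0430). They were not called in 2 and 4 of 6 fits without 1 library (up to 0.0707 and 0.178, both without mutant 2). The median of this list was 0.01, its mean -0.07 and its camera direction downward (adjusted p = 0.721).

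Among stress and growth lists, 1 of 29 tested immediate early genes fell, also adjusted over the list alone. Egr2 went from 285 ± 65.8 to 140 ± 34.6 CPM (-1.03, SE 0.23, adjusted p = 0.0432). It was called in 2 of 6 fits without 1 library (up to 0.138 without mutant 1). The list had a median of -0.12 (adjusted p = 0.105; 0.0398 with the block, where 1 rose and 7 fell; 0.00665 without control 1 and 2.02e-06 without mutant 3). None of 23 tested p53 target genes (median 0.03, camera downward, adjusted p = 0.825; 2 up with the block), 16 tested interferon response genes (0.34, adjusted p = 0.366) or 42 tested ribosomal protein genes (0.01, camera downward, adjusted p = 0.980) was called, nor when adjusted over the list alone. The interferon list passed without control 1 (0.0382) or mutant 1 (0.0338). Of 19 tested wound and inflammatory genes none was called, 3 rose and 2 fell adjusted over the list alone and 4 and 2 with the block (median -0.11, mean 0.41, adjusted p = 0.980). Of 6 tested cyclin-dependent kinase inhibitor genes 1 rose, also adjusted over the list alone (list median 0.33, adjusted p = 0.408). Cdkn1c went from 9.91 ± 1.96 to 64.3 ± 12.9 CPM (2.70, SE 0.24, adjusted p = 0.000526), and was called without each library in turn. Cdkn2a, the classical PRC1 target of cultured cells, was too low to test, with 0 control reads and 2, 0 and 10 mutant reads, and Cdkn2b was at 0.823 and 1.73 CPM (adjusted p = 0.490).

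Among the other subunits of PRC1 and PRC2 in the lists, 1 gene was called. The Polycomb group gene Sfmbt2 was outside these lists and rose, as given further below. None of 12 core and canonical PRC1 genes was called, nor when adjusted over the list alone (median 0.34, adjusted p = 0.252). With the block 1 rose, Cbx7 (9.07 and 17.1 CPM, adjusted p = 0.166, and 0.0339 with the block). Of 18 variant PRC1 genes 1 rose, also adjusted over the list alone, with a list median of 0.05 (adjusted p = 0.721). Bcorl1 went from 28.9 to 60.3 ± 14.4 CPM (1.06, SE 0.22, adjusted p = 0.0328). It was called in 1 of 6 fits without 1 library (up to 0.147 without control 1). Of 11 PRC2 genes none was called, and 1 rose and 1 fell adjusted over the list alone and with the block. Jarid2 was at 167 and 251 CPM (adjusted p = 0.102, and 0.00673 with the block). The methyltransferase gene Ezh2 was at 129 and 84.5 CPM (adjusted p = 0.0869, and 0.0146 with the block). The list median was -0.19 (adjusted p = 0.400, and 0.0141 with fry).

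Markers of other cell types in skin were mixed. Of 22 tested dermal fibroblast genes 3 rose, 5 adjusted over the list alone and 6 with the block. Thy1 rose from 9.61 ± 0.572 to 39.5 ± 15.2 CPM (2.04, SE 0.31, adjusted p = 0.00761). Fbn1, a microfibril protein, rose from 24.1 ± 11.6 to 87.1 ± 10.4 CPM (1.85, SE 0.32, adjusted p = 0.0137). Dlk1 rose from 4.26 ± 1.20 to 14.6 ± 3.72 CPM (1.77, SE 0.34, adjusted p = 0.0218). The collagen genes Col1a1 (132 and 102 CPM) and Col3a1 (91.7 and 77.2 CPM) were not called, and the list had a median of 0.22 (adjusted p = 0.116; 0.0417 without control 3 and 0.0338 without mutant 1). Fbn1 and Dlk1 were each called in 3 of 6 fits without 1 library, with adjusted p up to 0.0756 without control 1 and 0.118 without mutant 2. Of 16 tested infundibulum and sebaceous genes 2 fell, Pparg and Lrig1. Lrig1, a growth factor receptor antagonist of the upper follicle, fell from 242 ± 4.09 to 141 ± 5.43 CPM (-0.78, SE 0.13, adjusted p = 0.0135). It was called in 3 of 6 fits without 1 library (up to 0.0792 without mutant 1). Adjusted over the list alone 1 rose and 2 fell, with the block 1 and 3, and the median of 0.11, the mean of -0.08 and the downward camera direction differed in sign (adjusted p = 0.825). Of 16 tested immune genes 1 rose, also adjusted over the list alone. H2-Ab1 rose from 4.95 to 20.4 CPM (2.04, SE 0.46, adjusted p = 0.0476) and was called in 2 of 6 fits without 1 library (up to 0.174 without mutant 2). It also lost its call with DESeq2-type size factors (0.0514), the stricter filter (0.0511) and the GC and length correction (0.0594). The genes of its partners in antigen presentation, H2-Aa (-1.22, adjusted p = 0.462) and Cd74 (-0.95, adjusted p = 0.408), were not called. The immune list had a median of -0.52 (adjusted p = 0.314; 0.00188 without control 2 and 0.00833 without mutant 3).

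No gene was called, over all genes or adjusted over the list alone, among 8 tested endothelial genes (median 0.44, adjusted p = 0.400; 0.0481 without mutant 1) or 9 melanocyte genes (median -0.19, mean 0.01, adjusted p = 0.723). The same held for 12 Schwann and nerve genes (0.13, adjusted p = 0.825; 1 up with the block, Mbp) and 3 skeletal muscle genes (-0.89, adjusted p = 0.17; 0.0455 without mutant 2 and 0.0178 without mutant 3). Of 12 erythroid genes 1 could be tested, Alas2 (-0.01, adjusted p = 0.996), so that list had no set test. The genes of the sort were not called. Epcam was at 162 and 198 CPM (adjusted p = 0.653) and Itga6 at 734 and 756 CPM (adjusted p = 0.967). Ly6a, which encodes Sca1, was at 0.852 and 1.23 CPM (adjusted p = 0.807). It had 11, 8 and 23 reads in the controls and 22, 25 and 15 in the mutants. So low a transcript level argues against a Sca1-positive gate, although the stained protein was not measured here.

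The libraries mixed sexes within each group. Xist, expressed from the inactive X chromosome, was at 8872, 8741 and 9.19 CPM in controls 1 to 3 and at 11.1, 6343 and 15.0 CPM in mutants 1 to 3. The Y-linked Ddx3y was at 0.136, 0.125 and 122 CPM and at 110, 0.179 and 109 CPM. Of 5 tested sex genes none was called, nor when adjusted over the list alone (median 0.64, adjusted p = 0.721). The ribosomal RNA precursor Rn45s took 3.83% ± 0.281 of counts in controls and 5.16% ± 0.684 in mutants (n = 3 each, exact permutation test, two-sided, p = 0.1, the smallest possible). Genes at 1 CPM or more numbered 13273 ± 191 in controls and 13557 ± 64.2 in mutants (exact permutation p = 0.1). The shares of Malat1 (p = 0.9) and Neat1 (p = 0.8) did not separate the groups by the same exact test.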

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

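The sex term, the fits without the sex genes and Rn45s or without both libraries numbered 3, and the GC and length corrections were chosen after the data were seen. The direction of every named called gene held in all fits, and Ring1 was called in each at an adjusted p under 0.05, though it missed the stricter threshold of 0.01 (0.0113). The counts of 430 changed, 372 risen, 58 fallen and 389 at least 2-fold changed genes moved by over 1.5 times as follows. The cause was not tested, except that a stricter threshold passes fewer genes. DESeq2 gave 959, 728, 231 and 750 genes, the replicate block 1345, 873, 472 and 702, and the GC and length correction with the block 1120, 740, 380 and 634. A fit without both libraries numbered 3 gave 772, 583, 189 and 585, and an adjusted p under 0.01 gave 155, 140, 15 and 153. No filter gave 109 fallen genes, the sex term 97, and a test against a fold of 1.5 gave 223 changed. Among the genes and lists printed, the block changed no call other than those given with it. Leaving out 1 library gave 163 to 664 changed, 143 to 554 risen, 19 to 110 fallen and 162 to 577 at least 2-fold changed genes, and 20 to 38 of 41 named genes besides Ring1. Ring1 ran from -2.30 to -1.74 (adjusted p 0.0140 to 0.0412), Rnf2 from 0.11 to 0.27, and the difference in genes at 1 CPM from 174 to 359. Gene lists passing were 5 to 8 without 1 library, 8 with the sex term and 0 with an estimated correlation, against 5. Of 42 called named genes, Ring1 included, 20 were called in all 6 fits without 1 library and 19 in every refit at an adjusted p under 0.05. Beyond the counts above, 192 values gained a call, 116 lost one and 2936 kept their side. Among named genes not called, 20 of 1718 values over 8 of 100 genes changed sign, and 51 of 481 over 15 of 27 lists. The dermal papilla list was lost without the filter (adjusted p 0.0931), where the endothelial list passed (0.0140). The Hox list was lost with the stricter filter (0.143), fry (0.0954) and the GC and length correction without and with the block (0.241 and 0.436). The proliferation list was lost with fry (0.0954), while the PRC2 and cyclin-dependent kinase inhibitor lists passed (0.0141 each), so that 5 lists passed there too. With the GC and length correction, without and with the block, the placode and stem cell list passed (0.00403 and 0.000614), as did the immediate early list (0.00031 and 7.28e-05), and with the block the Hedgehog list (0.0151). With the sex term the immediate early (0.0106), immune (0.0187) and skeletal muscle (0.0388) lists passed, and without both libraries numbered 3 the immediate early list (0.000607). Depth limits genes under 1 CPM, where 14.7 to 18.3 reads or fewer stand behind a value.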

Other observations

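The tests of imprinted, germline, ion channel and synapse genes, of imprinted clusters, of the collagen sum, and of basal and differentiation genes against the proliferation list were chosen only after the results were seen. The bound of the collagen test was widened from the SE to the 95% interval, and differentiation was first tested on Krt1 and Krt10 (mean -0.58, SE 0.25) before the whole list was used, and the scaling test was made to require a shift of all genes by over 0.1 on the log2 scale, all with the values known. The 4 gene lists were drawn up because their genes stood out among the called ones, and the synapse and imprinted lists were revised after a first test. The deciding test was then moved to members that had not been called, and to a p adjusted over the 4 lists once the unadjusted values were known.

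Of 41 tested imprinted genes, which are expressed mainly from 1 parental copy, 10 rose and none fell (15 adjusted over the list alone). Sfmbt2, a Polycomb group gene, rose from 3.59 ± 0.434 to 61.6 ± 1.75 CPM (log2 fold change 4.10, SE 0.21, edgeR adjusted p = 3.18e-05). The growth factor receptor adaptor Grb10 rose from 33.4 to 215 ± 37.9 CPM (2.69, SE 0.19, adjusted p = 0.00026). The growth factor gene Igf2 rose from 677 ± 139 to 1474 ± 329 CPM (1.12, SE 0.21, adjusted p = 0.0218), and the noncoding Meg3 rose from 21.4 to 131 ± 56.0 CPM (2.61, SE 0.41, adjusted p = 0.00888). The called genes lay in 6 separate clusters on chromosomes 1, 2, 6, 7, 11 and 12, which argues against a rise of 1 cluster; Meg3, Rian, Rtl1 and Dlk1 share the one on chromosome 12, and Dlk1 and Cdkn1c are also members of lists described before. Over the whole list camera with an estimated correlation gave p = 0.0125. Among the 31 members not called, 21 had a positive fold change against 48.6% of 13915 other genes, and their adjusted p was 0.0702. A rise of the whole group beyond its called members therefore stays open as a hypothesis.

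Of 45 tested ion channel genes 11 rose and none fell (20 adjusted over the list alone), among them Cacna1h (1.35 to 25.8 ± 2.02 CPM, 4.23, SE 0.36, adjusted p = 0.000451) and Kcna1 (8.74 to 68.1 ± 9.40 CPM, 2.96, SE 0.35, adjusted p = 0.00234), calcium and potassium channel genes. Of 59 synapse genes 10 rose and none fell (16 adjusted over the list alone and 16 with the block), such as the scaffold genes Shank1 (22.6 to 88.9 ± 7.75 CPM, 1.98, SE 0.18, adjusted p = 0.000534) and Homer2 (14.3 to 95.3 ± 26.5 CPM, 2.73, SE 0.32, adjusted p = 0.00203). Of 17 germline genes 4 rose and none fell (5 adjusted over the list alone), among them Tdrd1, of the germ cell piRNA pathway (24.0 to 74.9 ± 7.07 CPM, 1.64, SE 0.17, adjusted p = 0.0011). With an estimated correlation the whole lists gave p = 0.00257, 0.0157 and 0.112. The members not called gave adjusted p of 0.0664, 0.0671 and 0.358 (unadjusted 0.0166, 0.0336 and 0.358), with 27 of 34, 34 of 49 and 8 of 13 positive. None of these groups was shown to rise beyond the genes called.

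More genes rose than fell (86.5% of calls). Scaling of the libraries would have to lower this share, and over 3 other scalings it was at least 84.9%, but these shifted the median of all genes by at most 0.05 on the log2 scale, so the bound set for this test could hardly be missed. With a correction for GC content and length and the replicate block, 66.1% rose, against 64.9% with the block alone and a bound of 60% set once the latter was known. This argues against GC content or length as the whole cause. A scaling fault shifts all genes of a library alike. The median log2 fold change was 2.14 for the 372 risen genes and -0.0033 for all tested genes, with 353 up and 36 down at least 2-fold. The TMM scaling itself centres the bulk of genes, and the risen genes were picked by the test, so these medians do not test the scaling. A shift common to all genes leaves the distance of the risen genes from the bulk unchanged, so a scaling fault does not account for that distance. Whether the bulk itself stayed level was not measured. The genotype stays open as a hypothesis for the excess of rises.

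Other splits of the 6 libraries gave at most 4 changed, 3 higher, 3 lower and 4 at least 2-fold changed genes against 430, 372, 58 and 389, and 1 of 10 splits, the real one, was as large for each. Up to 17 lists passed in another split against 5, with 5 of 10 splits at 5 or more; 10 splits are too few for a share under 0.05. The 3 other splits that part all replicate pairs called 0 genes. Every other split mixes controls and mutants on both sides, so a real difference between the groups adds to the spread within each side. Few called genes were therefore likely there, and their counts do not measure what chance alone would give.

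Thy1, Fbn1 and Dlk1, from the dermal fibroblast list, rose by 103 CPM in sum, and fibroblast RNA in the mutant libraries could give this. Against it, the sum of Col1a1, Col1a2 and Col3a1 changed by -38.1 CPM. The 95% interval of the difference between the sums (SE 65.9, half-width 183 CPM) treated them as independent, although both come from the same libraries. As computed, it does not exclude an equal rise in CPM. A rise by an equal factor is a different expectation. Thy1, Fbn1 and Dlk1 went from 38.0 ± 10.97 to 141 ± 17.2 CPM in sum. The 3 collagen genes went from 319 ± 83.6 to 281 ± 74.9 CPM. The sums argue against added RNA that raised both sets by the same factor. The share of these transcripts in fibroblasts of this skin was not measured, and Thy1, Fbn1 and Dlk1 were the called members of the list. The most abundant members, Fn1 (1045 and 1216 CPM) and Postn (811 and 862 CPM), were not called, while Sparc (431 and 684 CPM, adjusted p 0.00797) and Col5a1 (116 and 180 CPM, 0.0126) were called with the block, as were the dermal papilla genes Bmp3 (12.7 and 69.3 CPM, 0.00364) and Trps1 (94.3 and 192 CPM, 0.00656), the latter also a hair placode list member. Of the 25 listed genes, 22 were at 1 CPM or more in control follicle cells and 2, Dcn and Dlk1, are also imprinted list members; an EpCAM-positive gate, which the protocol gives for interfollicular epidermis, would remove fibroblasts, but the gate of these samples is not given in the sources used here. Expression by the follicle cells themselves therefore stays open, as does RNA of dermal cells, other than a rise of both sums by the same factor.

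Proliferation genes were lower, with a median of -0.54, a call that was lost with an estimated correlation (adjusted p = 0.491) and with fry (0.0954) and was also made in 4 of 9 other splits (lowest adjusted p 2.24e-05). With the preset correlation the list passed without each library in turn (adjusted p at most 5.03e-05). Since this test also passed in other splits, its p-values do not decide whether 1 library is the source. The median stayed between -0.575 and -0.367 over all alternatives, those without 1 library included, so its sign did not rest on 1 library. Dilution by cells other than keratinocytes would lower basal keratinocyte genes likewise, but their median was 0.0404 (SD 0.31). More suprabasal cells in the sort stay open: the interfollicular differentiation list had a median of 0.242 (SD 1.05, 22 of 34 positive, 7 up and 3 down with the block), with Krtdap at 0.62 (adjusted p = 0.145; 0.00578 with the block), Krt1 at -0.66 (0.195; 0.00154 with the block) and Krt10 at -0.47 (0.331). A lower cycling share in mutant follicles may be a candidate explanation, as may a shift between follicle cell populations within the gate, and neither was tested.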
